A study of Mus musculus with 6 samples.

How the data were processed

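RNA was measured in 6 libraries of mouse bone marrow cells, macrophages per the labels, sorted by flow cytometry for the surface protein F4/80, which the gene Adgre1 encodes, and for eGFP from an Epor reporter. The labels place 3 libraries in the F4/80+ Epor-eGFP+ group and 3 in the F4/80+ Epor-eGFP- group. Per the labels' protocols, total RNA was made into libraries with a TruSeq RNA kit. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

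The deposited values are FPKM, fragments per kilobase of gene scaled to the fragments of the library, in a single table of 11489 genes. Per the submitters' processing notes, bcl2fastq 2.19.1.403, Trimmomatic 0.35, TopHat2 2.1.0, Cufflinks 2.2.1 and the mouse build mm10 were used, and the notes as given here carry no role or order for these tools. The gene annotation, any filter and any scaling between libraries are not given in the sources used here. Every gene of the deposited FPKM table reaches at least 1.00 FPKM in some library. The library medians lie between 11.7 and 11.8 FPKM and the upper quartiles between 27.1 and 29.3 FPKM, so the libraries were already close to a common scale. FPKM values hold no read counts, so the depth of each library is unknown and no counting interval is given. Cufflinks shares reads between similar genes by estimation, so values of near-identical genes (globins, Ear genes, Cd209 genes, histones, ribosomal protein genes with pseudogenes) are uncertain singly.

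Column names give the group and a number from 0 to 2, while the labels number the samples from 1 to 3, so columns were assigned to a group and not to a single sample. Libraries are called by their column number. Libraries with the same number deviated together from their group means over the tested genes, with correlations of 0.25, 0.38 and 0.35 for numbers 0, 1 and 2, against −0.39 to 0.07 for pairs with different numbers. By the rule set for this check, correlations above 0.1 in every pair, the numbers behave as pairs in the data, although no label says what they mark. Deviations from a group mean sum to 0, so positive same-number correlations push those of other pairs down. Among the 6 ways to match the numbers between groups, only the actual match gave a mean correlation as high (1 of 6). A match by chance is therefore not excluded. The fit without a block stayed the primary fit, and the fit with the column number as a replicate block is an alternative.

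Genes with a mean of at least 1 FPKM over the 6 libraries were tested (10964 genes). limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with the group as the only term, with eBayes moderation and a mean-variance trend, with two-sided tests. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05 and no fold minimum. Fold changes are on the log2(FPKM + 1) scale, Epor-eGFP+ minus Epor-eGFP-, which understates the change of genes with low values. Means and SDs are of FPKM over 3 libraries.

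Of 34 gene lists, 10 hold markers of other cell types that an F4/80 gate on bone marrow could hold, and 24 hold functions. A list with at least 5 tested genes was tested with camera on the same fit with a preset correlation between genes of 0.01, and adjusted over the 33 lists tested. Camera with an estimated correlation and fry were run beside it, and ranges of a list's adjusted p cover the alternatives that keep the preset correlation. Camera compares the genes of a list with all other tested genes, whereas fry asks if the genes of a list move on balance in a single direction. The list of mitochondrially encoded genes had 0 genes in the table and was not analysed here.

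The genes named are 14 fixed genes, the 8 genes with the largest positive and the 8 with the largest negative log2 fold change (adjusted p under the threshold, a mean of at least 10 FPKM in the higher group, groups that do not overlap, no predicted genes), and up to 4 called members of each list with the largest absolute log2 fold change, or up to 3 with the highest FPKM where none was called. The groups, the tests, the lists, this rule and the alternatives, except those added later, were fixed before the data were examined. Genes named outside this rule are said to be chosen after their values were seen.

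The fits were tested on simulated data with the means and spreads of the 10964 tested genes and 200 changed genes. Of genes changed by a log2 fold of 1, 77.6% were recovered, of those changed by 2, 92.5%, and of those changed by 4, 100%. Of 187 calls, 7 were false (3.74%). With no list moved, camera called 0 of 33 lists, and with a single list moved it called 1. The simulated genes were independent of each other, which real genes are not. Far fewer genes were changed than the real fit called (2489 higher and 2883 lower), and same-numbered libraries were not made to deviate together. These rates may therefore not hold for the real comparison.

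Gene positions come from GENCODE M21 on GRCm38, the assembly that mm10 names, in which 11065 of the 11489 symbols were found and 11044 of them once. Alternatives changed the pseudocount (0.1 and 0.5), the filter (none, and 5 FPKM), the scaling (quantile normalization, a common total, the upper quartile, the median), the moderation (no trend, robust), the weights of the libraries, the replicate block, the thresholds and the list test, and left out each library in turn. Added after seeing the data were fits without both libraries numbered 2, list tests without Lyz2 and Prg2, and library weights estimated gene by gene.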

Results

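Gene expression was measured by RNA sequencing in F4/80+ cells sorted from mouse bone marrow into an Epor-eGFP+ group (3 libraries) and an Epor-eGFP- group (3 libraries). F4/80 is a surface protein of mouse macrophages, and Epor encodes the erythropoietin receptor. The labels name erythroblastic island macrophages, the macrophages around which erythroblasts mature in the bone marrow. Total FPKM per library ran from 467176 to 519650, and the read depth behind these values is unknown. Across genes, which are not independent replicates, Spearman correlations were 0.984 to 0.991 between Epor-eGFP- libraries, 0.973 to 0.989 between Epor-eGFP+ libraries and 0.908 to 0.953 between groups. The leading principal component separated the groups and held 78.9% of the variance, and the next held 11.5%.

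The comparison asked how F4/80+ cells marked by the Epor reporter differ from F4/80+ cells without it. Epor was higher in Epor-eGFP+ cells, at 5.96 ± 2.26 FPKM against 0.335 ± 0.105 (SD, n = 3 per group; log2 fold change 2.33, SE 0.25, limma adjusted p = 0.000842). Adgre1, which encodes F4/80, was at 167 ± 65.5 FPKM against 136 ± 3.85 and did not pass the test (log2 fold change 0.23, SE 0.24, adjusted p = 0.463). By an exact two-sided permutation test, p was 0.1 for Epor, the smallest that 3 against 3 libraries allow, and 0.7 for Adgre1. The direction of the Adgre1 difference rested on Epor-eGFP+ library 2, without which the log2 fold change was −0.07. Epor lies on chromosome 9 from 21958897 to 21963506 on the minus strand and Adgre1 on chromosome 17 from 57358691 to 57483527 on the plus strand (GRCm38), and FPKM values are for whole genes.

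Of 10964 genes tested, 2489 rose and 2883 fell in Epor-eGFP+ cells at an adjusted p below 0.05, and 46.3% of the called genes were higher. With each library rescaled to a common total, 3055 genes were higher and 2082 lower, a share of 59.5%. By a log2 fold change of at least 1, 539 genes rose and 481 fell, and by at least 2, 149 rose and 32 fell. The groups did not overlap in 6617 genes (60.4%), where chance gives 10%. Without Epor-eGFP+ library 0, 1611 genes rose and 2060 fell, and without both libraries numbered 2, 2216 rose and 2498 fell.

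Among the 8 largest rises by the naming rule were the genes of the C1q chains, Cd5l, Cd163 and Car1, while Fcna, which rose most, is in no list. Fcna, which encodes ficolin A, rose from 8.46 ± 4.06 to 555 ± 417 FPKM (log2 fold change 5.67, SE 0.58, adjusted p = 0.000739). Cd5l, which encodes a secreted scavenger receptor protein of macrophages, rose from 4.36 ± 2.24 to 272 ± 209 FPKM (5.41, SE 0.62). The genes of the C1q chains rose together, C1qa by 5.23, C1qc by 5.21 and C1qb by 5.02 on the log2 scale, and their summed FPKM was 2641 ± 1728 against 62.5 ± 13.9. Car1, the carbonic anhydrase of red cells, rose from 3.49 ± 1.67 to 157 ± 33.6 FPKM (5.18, SE 0.27). Itgad, an integrin alpha chain, rose by 5.02 (SE 0.50), and Cd163, the scavenger receptor for haemoglobin bound to haptoglobin, rose from 3.40 ± 0.857 to 147 ± 108 FPKM (4.82, SE 0.50). Epor-eGFP+ library 2 carried much of these means, which without it were 1672 FPKM for the C1q sum, 324 for Fcna, 159 for Cd5l and 86.8 for Cd163. Adjusted p of these 8 genes ran from 0.000229 for Car1 to 0.000979 for Cd5l. Fcna lies on chromosome 2 from 25624666 to 25628030, Cd5l on chromosome 3 from 87357881 to 87371073, and the C1q genes side by side on chromosome 4, C1qb from 136880129 to 136886187, C1qc from 136889804 to 136893065 and C1qa from 136895917 to 136898803.

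Of the 8 genes with the largest falls, Retnlg and Ifitm6 are in the neutrophil list, Vcan in the monocyte list and Alox15 in the eosinophil list, and the others are in no list. Serpinb2, an inhibitor of plasminogen activators, fell from 36.0 ± 6.46 to 2.82 ± 0.921 FPKM (log2 fold change −3.29, SE 0.20, adjusted p = 0.000261). Alox15, a lipoxygenase, fell from 872 ± 155 to 104 ± 47.6 FPKM (−3.14, SE 0.30). Thbs1 (−2.75), Retnlg (−2.70), Ifitm6 (−2.70), Slfn1 (−2.50), Vcan, which encodes versican (−2.49), and Arhgef37 (−2.46) fell as well. Adjusted p of these 8 genes ran from 9.68e-05 for Ifitm6 to 0.00383 for Thbs1.

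Apart from Adgre1, every gene of the 14 fixed in advance rose. Vcam1, an adhesion molecule that binds erythroblasts, rose from 31.8 ± 8.07 to 559.9 ± 388 FPKM (log2 fold change 3.90, SE 0.46, adjusted p = 0.00108). Siglec1, the sialic acid receptor CD169, rose from 7.21 ± 1.47 to 67.7 ± 45.0 FPKM (2.88, SE 0.42, adjusted p = 0.00217). Mrc1, the mannose receptor, rose by 4.17 (SE 0.41), Mertk, a receptor for apoptotic cells, by 4.12 (SE 0.38), and Spic, a transcription factor of red pulp macrophages, by 4.08 (SE 0.41). Igf1 rose by 3.91 (SE 0.44), Il18 by 2.03 (SE 0.47) and Dnase2a, the lysosomal DNase that digests expelled erythroid nuclei, by 1.12 (SE 0.25, adjusted p = 0.0103). Klf1, an erythroid transcription factor, rose from 1.54 ± 0.402 to 19.3 ± 4.03 FPKM (2.99, SE 0.18, adjusted p = 0.000261). Within Epor-eGFP+, Vcam1, Siglec1, Cd163, Mrc1, Mertk and Spic were highest in library 2 and lowest in library 1, and Klf1 was highest in library 0. Without library 2 the Epor-eGFP+ mean was 340.2 FPKM for Vcam1 and 42.3 for Siglec1.

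**Figure D1:**
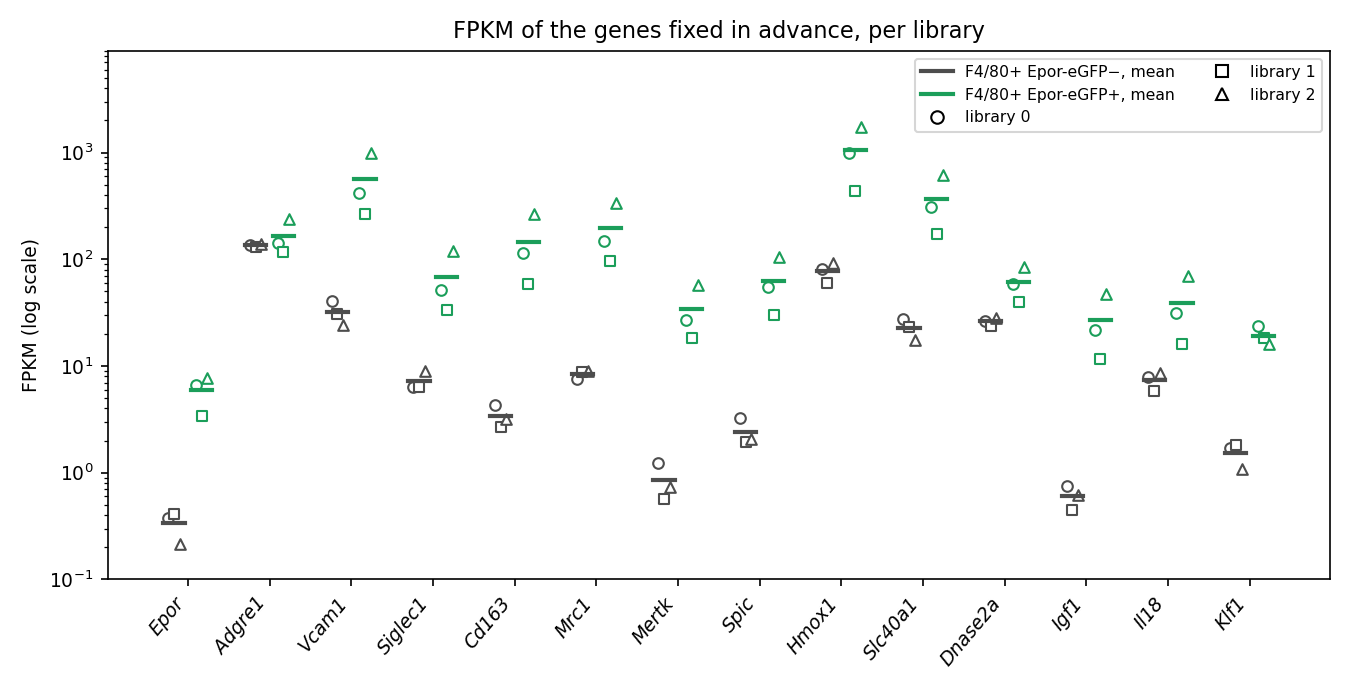
FPKM of the 14 genes fixed in advance on a log axis, with a symbol for each library (circle 0, square 1, triangle 2) and a bar for the mean of each group. The Epor-eGFP+ libraries lie above the Epor-eGFP- libraries in every gene but Adgre1, where the means are 167 and 136 FPKM.

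Genes of iron and heme handling rose in Epor-eGFP+ cells, with 17 of 26 tested members higher, 3 lower and 6 without a call (median log2 fold change 1.08, camera adjusted p = 0.000189, adjusted p = 0.665 with an estimated correlation). Hmox1, which degrades heme, rose from 78.3 ± 16.3 to 1059 ± 661 FPKM (3.55, SE 0.46), and Slc40a1, the iron exporter ferroportin, from 22.9 ± 5.23 to 364 ± 226 FPKM (3.77, SE 0.43), or to 239 without Epor-eGFP+ library 2. Cd163 and Spic are in this list too. Of the heme biosynthesis genes, 10 of 15 rose, 1 fell and 4 had no call (median 0.84, camera adjusted p = 0.000365, adjusted p = 0.665 with an estimated correlation). Cpox (1.31, SE 0.13), Alad (1.15, SE 0.14) and Uros (1.07, SE 0.11) were among those that rose. Over 22 alternatives with the preset correlation the median of this list ran from 0.54 to 0.98 and its camera adjusted p from 0.000113 to 0.0180. Cpox and Uros are also in the erythroid list, whose median was 1.78 in the same libraries. Of 16 tested secreted factors acting on erythroid cells, 10 rose, 4 fell and 2 had no call (median 1.49, camera adjusted p = 0.0129, adjusted p = 0.665 with an estimated correlation). Sphk1, a sphingosine kinase, rose from 0.0606 ± 0.0200 to 8.32 ± 1.85 FPKM (3.12, SE 0.15), Gdf15 by 2.98 (SE 0.23) and Gas6, a ligand of Mertk, by 2.93 (SE 0.38). Within Epor-eGFP+, Sphk1 and Gdf15 were highest in library 0 and lowest in library 2, as Klf1 was, while Gas6 was highest in library 2. Which cells carried these transcripts was not tested. Without genes under 5 FPKM the list of secreted factors lost its call (adjusted p = 0.101), and over 22 alternatives with the preset correlation its adjusted p ran from 0.00300 to 0.101. With p-values adjusted over the list alone, 18 iron and heme genes were higher and 3 lower, 11 and 1 of the heme biosynthesis genes, and 11 and 4 of the secreted factors.

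The lists of island adhesion, apoptotic clearance, lysosome, complement and alternative activation held strong rises beside falls and did not pass camera. Of 20 adhesion and surface genes, 9 rose, 5 fell and 6 had no call (median 0.20, adjusted p = 0.186). Timd4, a phosphatidylserine receptor, rose from 0.514 ± 0.262 to 33.2 ± 26.1 FPKM (4.21, SE 0.53), or to 18.8 without Epor-eGFP+ library 2. Of 33 genes of apoptotic cell and nucleus clearance, 18 rose, 10 fell and 5 had no call (median 1.12, adjusted p = 0.0971), with the C1q genes and Cd5l at the top. Of 46 lysosome genes, 14 rose, 6 fell and 26 had no call (median 0.18, adjusted p = 0.129). Their median was 0.28 without Epor-eGFP+ library 1 and ran from 0.058 to 0.28 over 22 alternatives with the preset correlation. Ctsk, which encodes cathepsin K, rose from 0.339 ± 0.0924 to 36.3 ± 20.2 FPKM (4.65, SE 0.38), Atp6v0d2, a proton pump subunit, by 2.63 (SE 0.32), Acp5 by 2.47 (SE 0.26) and Lgmn by 2.13 (SE 0.41). Within Epor-eGFP+, Ctsk, Atp6v0d2 and Acp5 were highest in library 0, while Lgmn was highest in library 2, as Vcam1 and Siglec1 were. Which cells carried Ctsk, Atp6v0d2 and Acp5 was not tested, and the lists of other cell types include none for osteoclasts. Of 16 complement genes, 9 rose, 4 fell and 3 had no call (median 1.10, adjusted p = 0.155), and Vsig4, a complement receptor, rose by 3.11 (SE 0.48). The complement median ran from 0.51 to 1.41 over 22 alternatives with the preset correlation. Of 19 alternative activation genes, 10 rose, 5 fell and 4 had no call (median 1.4032, adjusted p = 0.224), including Cd209f (4.48, SE 0.55) and Cd209g (3.04, SE 0.56), whose close paralogs make each estimate uncertain. With genes under 5 FPKM left out, the median of that list was −0.09. Under quantile normalization the clearance list (adjusted p = 0.0430) and the lysosome list (0.0167) passed, without Epor-eGFP+ library 1 they passed as well (0.00746 and 0.00872), and without Epor-eGFP- library 2 the lysosome list did (0.0464). Over 22 alternatives with the preset correlation their adjusted p ran from 0.00746 to 0.176 and from 0.00872 to 0.356, and with an estimated correlation both were at 0.818. Adjusted over the list alone, 9 adhesion genes were higher and 6 lower, 18 and 11 clearance genes, 14 and 6 lysosome genes, 9 and 5 complement genes, and 10 and 6 alternative activation genes.

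Erythroid genes rose together. Of 40 tested members of the erythroid list, 25 rose, 2 fell and 13 had no call (median 1.78, camera adjusted p = 2.565e-09, adjusted p = 0.665 with an estimated correlation). Ermap and Rhd, genes of red cell surface proteins, rose by 3.65 (SE 0.16) and 3.63 (SE 0.18), and the water channel gene Aqp1 by 3.46 (SE 0.32), beside Car1 and Klf1. Of the erythroid genes, 25 were higher and 2 lower when adjusted over the list alone. The 5 globins, chosen after their values were seen, did not pass in the fit without a block and passed in the fit with the replicate block. Hba-a1 was at 298 ± 247 FPKM against 97.3 ± 139 (log2 fold change 2.37, adjusted p = 0.139, and 0.0108 with the replicate block), and with the block the adjusted p of the 5 ran from 0.00141 to 0.0271. Each was higher in Epor-eGFP+ for all 3 column numbers. The summed FPKM of 5 globin genes was 63.1, 32.2 and 771 in Epor-eGFP- libraries 0, 1 and 2, and 727, 216 and 1686 in Epor-eGFP+ libraries 0, 1 and 2.

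Most of the neutrophil and monocyte genes tested fell. Of 31 neutrophil genes, 23 fell, 5 rose and 3 had no call (median −0.98, camera adjusted p = 0.000257, adjusted p = 0.746 with an estimated correlation). Retnlg fell from 1979.9 ± 348 to 331 ± 189 FPKM, Padi4 by 2.36 (SE 0.18) and Mmp8 by 2.34 (SE 0.16) on the log2 scale. Of the 5 that rose, Clec12a rose by 0.23 and the others were Mpo (2.16, SE 0.28), Elane (2.33, SE 0.24), Prtn3 (2.16, SE 0.22) and Ctsg (2.17, SE 0.22), the azurophil granule genes that promyelocytes transcribe, chosen after their values were seen. Their summed FPKM was 8270.3 ± 958 against 1862 ± 703, while that of the specific granule genes Ngp, Camp, Ltf and Lcn2, chosen in the same way, was 5181 ± 454 against 13633 ± 3101. S100a8 and S100a9, chosen in the same way, summed to 9160 ± 1727 FPKM against 16533 ± 3865. Transcripts of these granulocyte genes thus stayed abundant in Epor-eGFP+ cells. Of 23 monocyte genes, 17 fell, none rose and 6 had no call (median −1.36, camera adjusted p = 2.68e-06, adjusted p = 0.665 with an estimated correlation). Fn1, fibronectin, fell from 750.2 ± 139.9 to 144 ± 30.4 FPKM (−2.38, SE 0.18), Ms4a4c by 1.87 (SE 0.26) and S100a4 by 1.80 (SE 0.27). Higher and lower were 5 and 23 neutrophil genes, and 0 and 17 monocyte genes, when adjusted over the list alone.

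**Figure D2:**
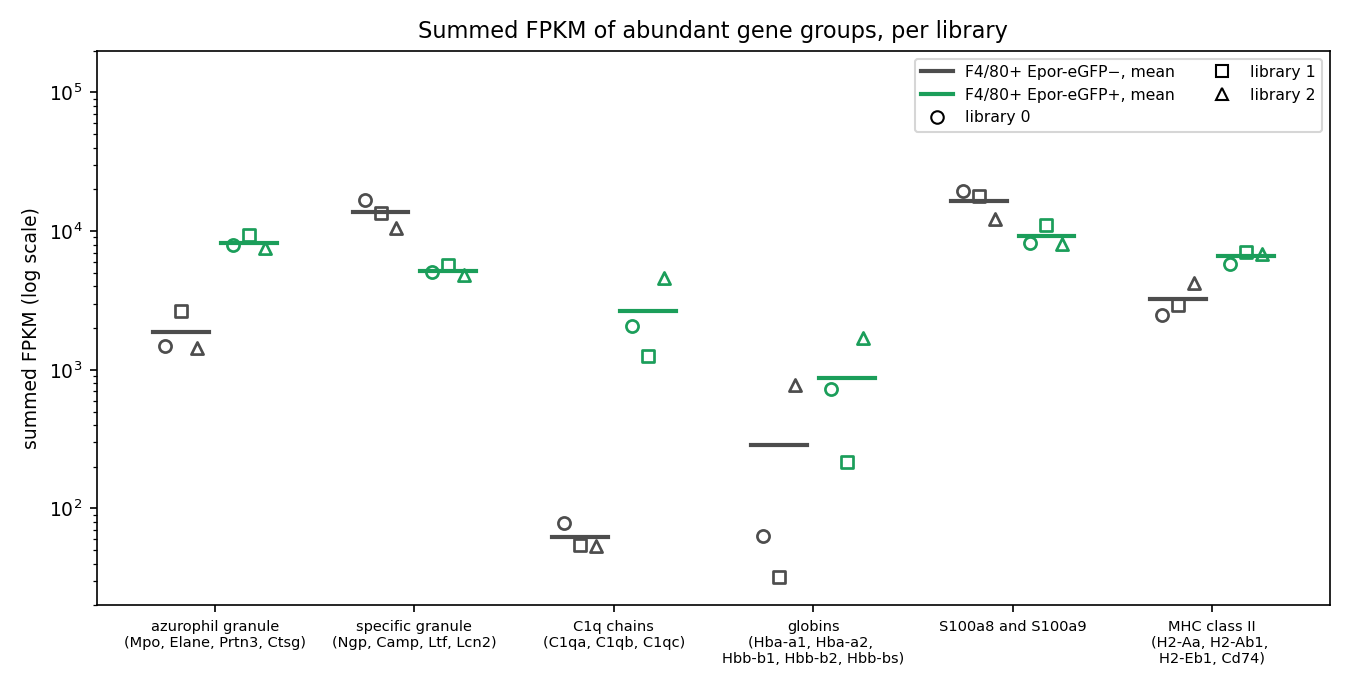
Summed FPKM of abundant gene groups on a log axis, with a symbol for each library and a bar for the mean of each group of 3. The azurophil granule genes are at 8270.3 FPKM in Epor-eGFP+ against 1862 in Epor-eGFP-, and the globins are highest in library 2 of each group.

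The other lists of cell type markers did not pass camera. Of 16 eosinophil genes, 8 fell, 4 rose and 4 had no call (median −0.63, adjusted p = 0.249), with falls of Alox15, Adora3 (−2.06, SE 0.17) and Ear1 (−1.35, SE 0.29), which has close paralogs, and a rise of Ltc4s (1.72, SE 0.43). The eosinophil gene Prg2 had a log2 fold change of −4.29 with a listed 0 in Epor-eGFP+ library 0 and of 0.17 without it. Over 22 alternatives with the preset correlation, Lyz2 and Prg2 left out being 1 of them, the eosinophil median ran from −0.78 to −0.42. Its camera adjusted p ran from 0.0960 to 0.409. Of 11 T and NK genes, 7 fell, 3 rose and 1 had no call (median −0.97, adjusted p = 0.375). Cd4 rose from 1.17 ± 0.367 to 36.4 ± 24.4 FPKM (3.93, SE 0.41, and 22.4 FPKM without Epor-eGFP+ library 2) and Nkg7 by 1.80 (SE 0.22), while Il2rb fell by 1.39 (SE 0.32) on the log2 scale. Within Epor-eGFP+, Cd4 was highest in library 2 and lowest in library 1, as Vcam1 was, while Nkg7 was highest in library 1. Which cells carried Cd4 and Nkg7 was not tested. Of 19 B lineage genes, 4 rose, 1 fell and 14 had no call (median −0.05, mean 0.17, camera direction up, adjusted p = 0.635), and the sign of the median turned under rescaling by the total or the upper quartile. Jchain, the joining chain of immunoglobulins, rose by 2.71 (SE 0.47). Of 16 megakaryocyte and platelet genes, 2 rose, 1 fell and 13 had no call (median 0.38, adjusted p = 0.224), with an adjusted p of 0.0222 in the fit with the replicate block, up to 0.578 over 21 alternatives with the preset correlation and 0.818 with an estimated correlation. Pf4 rose by 1.99 (SE 0.51) and Clec1b by 1.64 (SE 0.31). Of 9 stroma and endothelium genes, 5 rose, 1 fell and 3 had no call (median 1.21, adjusted p = 0.154), with Kitl at 3.07 ± 2.09 FPKM (1.94 without Epor-eGFP+ library 2) against 0.110 ± 0.0528 and Cxcl12 at 3.98 ± 1.13 against 0.779 ± 0.287. Of 15 dendritic cell genes, 3 rose, 2 fell and 10 had no call (median −0.22, adjusted p = 0.770), with Cd83 (1.66, SE 0.27) and Itgax (1.32, SE 0.10) higher and Flt3 (−1.15, SE 0.13) lower. Of 16 stem and progenitor genes, 1 rose, Myb (1.15, SE 0.21), 3 fell and 12 had no call (median −0.30, adjusted p = 0.386). When adjusted over the list alone, the counts higher and lower were 4 and 9 for eosinophil, 3 and 7 for T and NK, 3 and 1 for B lineage, 2 and 1 for megakaryocyte, 6 and 2 for stroma, 3 and 2 for dendritic and 1 and 3 for stem cell genes.

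Genes common to macrophages as a class moved both ways. Of 20 macrophage core genes, 6 rose, 4 fell and 10 had no call (median 0.20, adjusted p = 0.635), with Mertk, Maf (2.66, SE 0.32) and Lgmn among those that rose. Without Epor-eGFP+ library 2 that median was −0.09, and without Epor-eGFP- library 2 it was −0.05. Lyz2 is listed at 0 in Epor-eGFP- library 2, at 10411 and 10692 FPKM in Epor-eGFP- libraries 0 and 1, and at 3047, 3914 and 3277 in the Epor-eGFP+ libraries. Prg2, an eosinophil gene, is listed at 0 in Epor-eGFP+ library 0, at 10348 and 11088 in Epor-eGFP+ libraries 1 and 2, and at 12114, 9318 and 7567 in the Epor-eGFP- libraries. Lyz2 and Prg2 were chosen after their values were seen. Of 24 transcription factors of tissue macrophages, 6 rose, 11 fell and 7 had no call (median −0.31, mean 0.22, camera direction down, adjusted p = 0.375). Nr1h3, the nuclear receptor LXR alpha, rose from 1.78 ± 0.285 to 38.2 ± 20.1 FPKM (3.70, SE 0.33) beside Spic, and Pparg rose by 1.80 (SE 0.37). Of the core genes 6 were higher and 4 lower, and of the transcription factors 7 and 11, when adjusted over the list alone.

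Interferon response genes fell in Epor-eGFP+ cells. Of 31 tested, 21 fell, none rose and 10 had no call (median −0.60, camera adjusted p = 4.98e-05, adjusted p = 0.818 with an estimated correlation, fry adjusted p = 0.0515). Oas3 fell by 1.55 (SE 0.22) on the log2 scale, Zbp1 by 1.48 (SE 0.21) and Ifi27l2a by 1.47 (SE 0.30). Integrin and cytoskeleton genes of phagocytes fell as well, with 21 of 26 lower, 3 higher and 2 without a call (median −0.63, camera adjusted p = 1.80e-05, adjusted p = 0.665 with an estimated correlation). Itgb7 fell from 196 ± 28.5 to 49.9 ± 1.76 FPKM (−1.94, SE 0.11) and Lsp1 from 521 ± 134 to 139 ± 13.7 FPKM (−1.87, SE 0.18), while Itgad and Itga9 (2.74, SE 0.32) rose. Of 25 genes of Epo receptor and STAT5 signalling, 12 fell, 2 rose and 11 had no call (median −0.45, camera adjusted p = 0.0145, adjusted p = 0.665 with an estimated correlation). Mcl1 fell by 1.04 (SE 0.10) and Cish by 0.91 (SE 0.11), while Tfrc, the transferrin receptor, rose by 1.68 (SE 0.18) and Socs2 by 0.95 (SE 0.18). Epor itself, which rose by 2.33, is not in this list. Neutrophil genes (median −0.98) and monocyte genes (median −1.36) were lower in the same libraries. In counts adjusted over the list alone, 0 interferon genes were higher and 21 lower, 3 and 21 integrin and cytoskeleton genes, and 2 and 14 Epo receptor and STAT5 genes.

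MHC class II genes were higher by several members, though the list did not pass. Of 11 genes, 5 rose, 1 fell and 5 had no call (median 0.44, adjusted p = 0.196), with an adjusted p of 0.0175 without Epor-eGFP- library 2, up to 0.613 over 22 alternatives with the preset correlation and 0.818 with an estimated correlation. H2-Eb1 rose from 313 ± 65.3 to 845 ± 84.1 FPKM (1.45, SE 0.17), H2-Aa by 1.20 (SE 0.19) and H2-Ab1 by 1.13 (SE 0.20). Of 21 pro-inflammatory genes, 8 fell, 5 rose and 8 had no call (median −0.38, adjusted p = 0.386), with Nlrp3 lower (−1.36, SE 0.16) and Cd86 (1.66, SE 0.34), Il1a (1.49, SE 0.24) and Cxcl9 (1.41, SE 0.31) higher. Of 24 genes of dissociation and immediate early response, 8 fell, 3 rose and 13 had no call (median −0.37, adjusted p = 0.145), with an adjusted p of 0.0393 in the fit with the replicate block. Nr4a1 fell by 1.70 (SE 0.30) and Zfp36 by 1.61 (SE 0.37) on the log2 scale. Without Epor-eGFP+ library 1 the median of the dissociation list was −0.58. Its adjusted p was then 0.0285, the lowest of 22 alternatives with the preset correlation, the highest of these was 0.309, and with an estimated correlation it was 0.818. Adjusted over the list alone, 6 MHC class II genes were higher and 1 lower, 5 and 8 pro-inflammatory genes, and 3 and 8 dissociation genes.

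The medians of the cell cycle, ribosomal and oxidative phosphorylation lists were positive but small, and most genes of each list had no call. Over all tested genes, 2489 of 10964 rose. Of 32 cell cycle genes, 9 rose, none fell and 23 had no call (median 0.34, camera adjusted p = 0.000365, adjusted p = 0.818 with an estimated correlation, fry adjusted p = 0.173), with Ccnb1 (0.80, SE 0.15) and Ube2c (0.61, SE 0.12) first. Of 81 genes of nuclear oxidative phosphorylation, 33 rose, 4 fell and 44 had no call (median 0.19, camera adjusted p = 0.000137, adjusted p = 0.818 with an estimated correlation). Atp5g1 rose from 66.2 ± 6.02 to 124 ± 1.42 FPKM (0.90, SE 0.08). Of 81 cytosolic ribosomal protein genes, 16 rose, none fell and 65 had no call (median 0.10, camera adjusted p = 0.00495, adjusted p = 0.818 with an estimated correlation, fry adjusted p = 0.193). Rpl12 rose from 891 ± 24.4 to 1298 ± 61.6 FPKM (0.54, SE 0.09), and without Epor-eGFP- library 1 the ribosomal list lost its call (adjusted p = 0.0755, the highest of 22 alternatives with the preset correlation, from 1.50e-06). Its median without that library was 0.066. Erythroid genes (median 1.78) were higher in the same libraries. Of 24 replication dependent histone genes, 2 rose, 2 fell and 20 had no call (median 0.09, adjusted p = 0.386), and under quantile normalization the median was −0.06. Hist1h2bc rose by 1.34 (SE 0.36), though reads of histone genes are hard to assign. Adjusted over the list alone, 7 cell cycle genes were higher and 0 lower, 32 and 4 oxidative phosphorylation genes, 9 and 0 ribosomal genes, and 0 and 0 histone genes.

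Lipid uptake and efflux genes rose in part. Of 24 tested, 9 rose, 3 fell and 12 had no call (median 0.52, adjusted p = 0.154), with an adjusted p of 0.0226 without Epor-eGFP+ library 1, up to 0.316 over 22 alternatives with the preset correlation and 0.818 with an estimated correlation. Beside Nr1h3, its target Abca1 rose to 18.0 ± 10.1 FPKM (2.15, SE 0.38) and Lpl, lipoprotein lipase, by 2.06 (SE 0.26), while Apoc2 fell by 2.27 (SE 0.24) on the log2 scale. Of 23 cholesterol synthesis genes, 5 rose, 4 fell and 14 had no call (median 0.01, adjusted p = 0.729), and under quantile normalization the sign of the median turned. Fdps (0.68, SE 0.14) and Dhcr7 (0.67, SE 0.08) rose. Of 21 glycolysis genes, 9 fell, 4 rose and 8 had no call (median −0.02, adjusted p = 0.488), and the sign of the median turned under rescaling by the total or the upper quartile. Slc2a3, a glucose transporter, fell from 41.6 ± 9.89 to 11.7 ± 2.37 FPKM (−1.74, SE 0.20), and Pdk1 rose by 0.95 (SE 0.10). Adjusted over the list alone, 9 lipid genes were higher and 3 lower, 5 and 4 cholesterol synthesis genes, and 4 and 9 glycolysis genes.

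**Figure D3:**
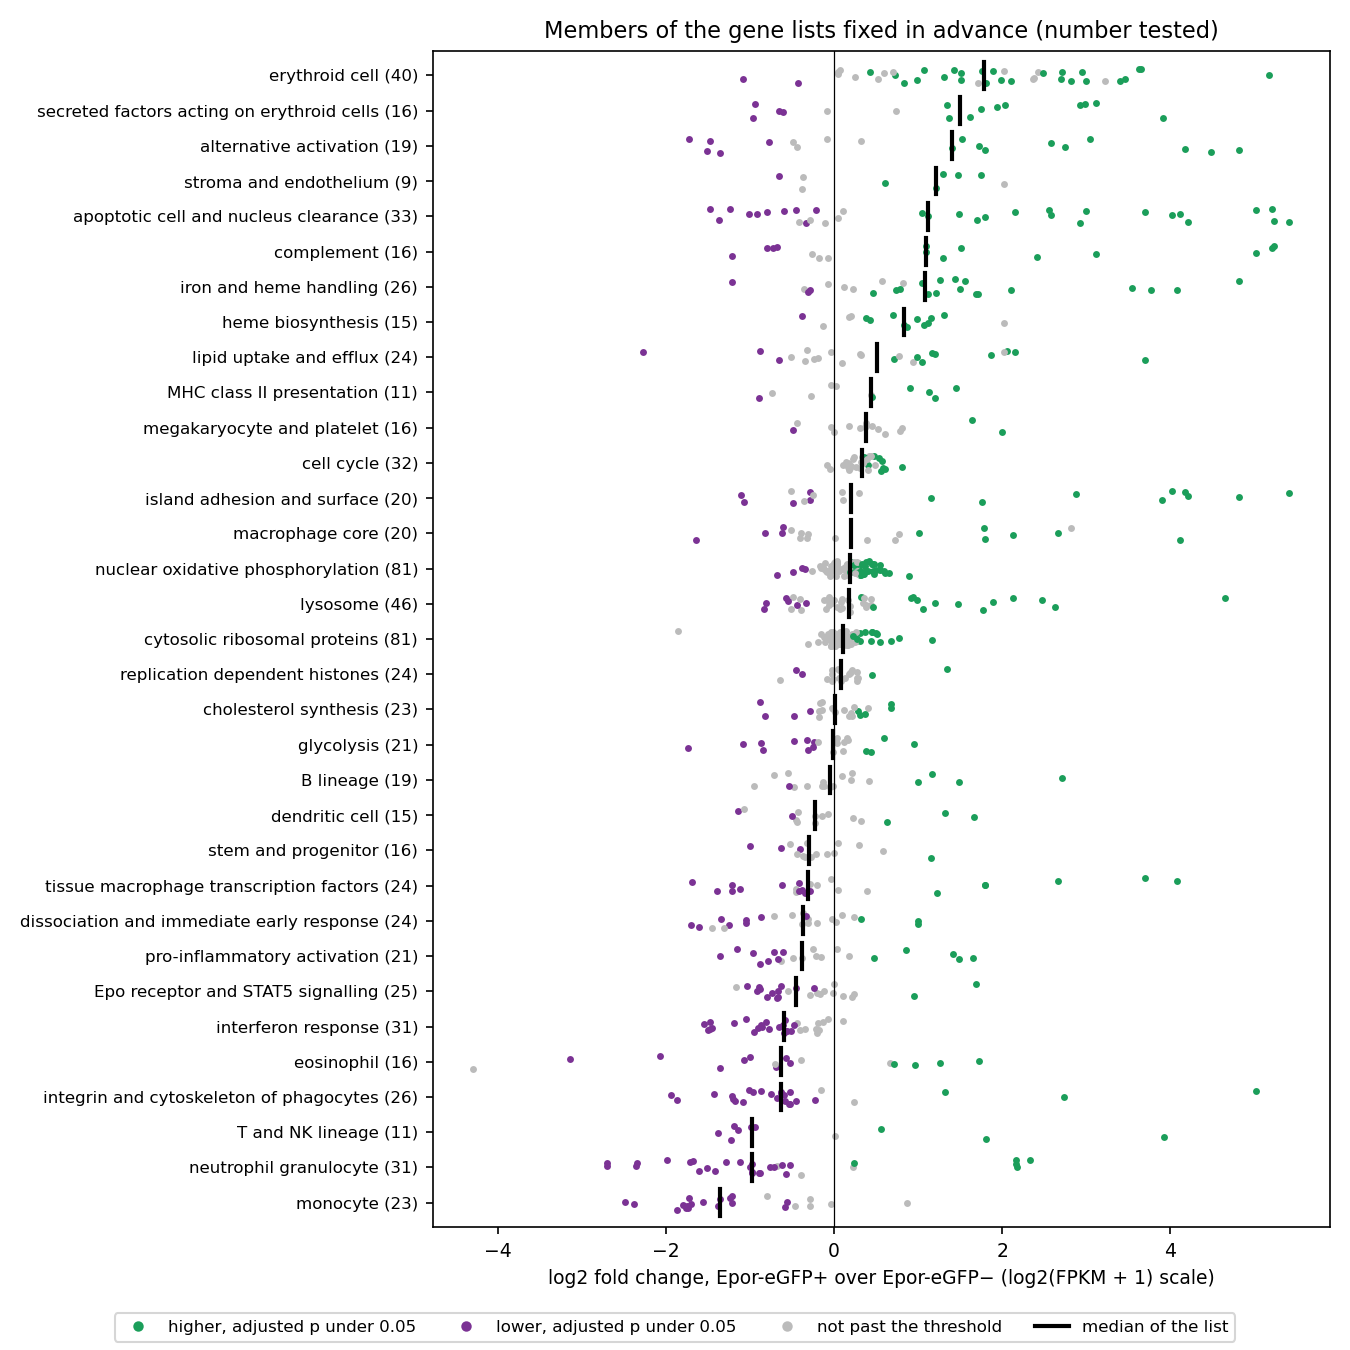
Log2 fold change of each tested member of the 33 lists, with the number tested beside each name and a bar at the median of each list. The erythroid list has the highest median (1.78) and the monocyte list the lowest (−1.36).

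Camera called 12 of 33 lists, 7 up and 5 down, and with an estimated correlation it called 0, with 2 lists at an unadjusted p below 0.05 and a lowest unadjusted p of 0.0360. Fry called 12 lists, of which 9 were called by camera in the same direction, and it added stroma and endothelium (adjusted p = 0.00368), complement (0.0429) and pro-inflammatory activation (0.0488). It did not call cell cycle (0.173), interferon response (0.0515) or cytosolic ribosomal proteins (0.193). Other divisions of the 6 libraries into 3 against 3 gave between 7 and 22 called lists. These divisions mix the groups and keep part of their difference, so these counts do not show what chance alone gives.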

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

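The fits without both libraries numbered 2, with Lyz2 and Prg2 left out of the list tests and with library weights estimated gene by gene were chosen after the data were seen, and the other alternatives were set beforehand. The values of named genes under the alternatives, counted without Epor and Adgre1, numbered 2572. Of these, 2523 kept their direction and side of the threshold and 49 lost their call. Adgre1, which was not called, turned sign as given below. The 16 genes with the largest changes kept their call in every alternative run. The 788 list values changed in 17 lost calls, 14 gained calls and 20 turned signs, none of the last with a call on either side. None of these changes came from the list tests without Lyz2 and Prg2. The cause of these changes was not tested except where stated. Default library weights, whose estimate did not converge and gave Epor-eGFP+ library 0 a weight of 25.4, called 3998 genes higher and 4258 lower, and weights estimated gene by gene 3288 and 3569. With a minimum log2 change of 1, 539 and 481 genes passed, by construction fewer. Leaving out a library gave 1611 (without Epor-eGFP+ library 0) to 2428 genes higher (without Epor-eGFP+ library 2), with fewer samples in each fit. Adgre1 ran from −0.069 without Epor-eGFP+ library 2 to 0.45 without library 1, and was −0.051 without both libraries numbered 2. Camera with an estimated correlation called 0 function lists and 0 cell type lists, 2 at an unadjusted p under 0.05, while fry called 12 lists in all. Medians turned to −0.086 (alternative activation, 5 FPKM filter), −0.0068 (cholesterol synthesis, quantile normalization) and −0.064 (histones, quantile normalization). With a common total, B lineage was 0.047 and glycolysis 0.047, and by the upper quartile 0.0092 and 0.018. With default library weights, macrophage core was −0.16 and glycolysis 0.035, and glycolysis was 0.033 with gene by gene weights. Without both libraries numbered 2, macrophage core was −0.24 and B lineage 0.23. Over single libraries left out, macrophage core ran from −0.091 (Epor-eGFP+ 2) to 0.41 (Epor-eGFP+ 1), B lineage from −0.42 (Epor-eGFP- 1) to 0.23 (Epor-eGFP- 2), cholesterol synthesis from −0.031 (Epor-eGFP+ 1) to 0.11 (Epor-eGFP- 1) and glycolysis from −0.10 (Epor-eGFP- 2) to 0.0039 (Epor-eGFP- 1). The replicate block by column number gave 3066 genes higher and 3335 lower, within 1.5 times the counts without it, and changed the call of the megakaryocyte list (adjusted p = 0.0222) and the dissociation list (0.0393) and of no other list, and it called the 5 globins. Epor was not tested with the 5 FPKM filter. Without read counts, no limit from depth can be given for genes near 0 FPKM.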

Other observations

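Chosen after the values they measure were seen were the tests of gene groups by symbol, the globin comparison and the tests of a fixed ratio. So were the tests on differences between the Epor-eGFP+ libraries, and each later form was chosen after the first was seen. The splits of the libraries and the tests on further promyelocyte and erythroid progenitor genes were set before their result was seen.

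Most Mrpl and Mrps genes of the mitochondrial ribosome and Timm genes rose in Epor-eGFP+ cells, and most Klf, Sp, Kdm and Map genes fell. Among 178 groups of at least 8 tested genes with the same symbol stem, each tested in both directions (356 one-sided Fisher's exact tests with Benjamini-Hochberg adjustment), 28 of 48 Mrpl, 20 of 29 Mrps and 12 of 13 Timm genes rose and 2, 0 and 1 fell (adjusted p = 2.24e-05 each, medians 0.32, 0.32 and 0.39), and of 9 Coq genes of ubiquinone synthesis 7 rose and 1 fell (adjusted p = 0.0364, median 0.43). Tomm genes, also of mitochondrial import, did not pass, with 4 of 9 higher and 0 lower (adjusted p = 0.687). Mrpl12 rose from 44.1 ± 4.01 to 77.5 ± 2.16 FPKM and Timm9 by 0.86 on the log2 scale. Lower were 9 of 12 Klf genes (adjusted p = 0.0347, median −0.997), 7 of 8 Sp genes (0.0347, −0.54), 11 of 17 Kdm genes of histone demethylases (0.0438, −0.29) and 18 of 32 Map genes, many of them kinases (0.0278, −0.42), while 1 Klf gene (Klf1, 2.99), 1 Kdm gene (Kdm8) and 0 Sp and Map genes rose. Klf2 fell from 85.0 ± 10.1 to 26.1 ± 6.10 FPKM and Kdm6b by 0.97 on the log2 scale. The direction of these 8 medians was the same under each scaling tried. In the same libraries the erythroid list (median 1.78) and Mpo, Elane, Prtn3 and Ctsg (4.44-fold in summed FPKM) were higher, and the monocyte (median −1.36) and neutrophil (median −0.98) lists lower. Genes of a stem are not independent of each other, and these genes were chosen after their values were seen. A stem is the leading letters of a symbol, so the genes of a stem need not be a single family.

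In the 10 splits of the 6 libraries into 3 against 3, the real split gave 2489 genes higher and 2883 lower by limma, and the highest of the other splits gave 0 by limma, with 649 at an unadjusted p under 0.05 against 6213. The real split alone, 1 of 10, gave as many genes in either direction, and 8 of 10 gave as many called lists, with 12 in the real split and 22 in the highest other. With 10 splits the share cannot fall under 0.05. Each other split held libraries of both groups on each side. The group difference thus widened the spread within its sides and remained in part between them. The counts of genes and lists from the other splits therefore do not show what chance alone gives. Of the splits that part all 3 column numbers, the real split gave 12 lists and the other three gave 13, 13 and 14, with 13, 45 and 1 genes at an unadjusted p under 0.05.

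Mpo, Elane, Prtn3 and Ctsg rose while most neutrophil genes fell. Of 14 further promyelocyte genes in no list of the report, 9 rose and 1 fell (median 0.69). Granulocyte progenitors in or attached to the Epor-eGFP+ material would give such a rise, although 12 of the 14 averaged at least 10 FPKM in Epor-eGFP- cells. Whether the F4/80 gate removed free progenitors was not tested. The specific granule genes summed to 5181 FPKM in Epor-eGFP+ and 13633 in Epor-eGFP- cells. A fixed ratio was tested against 54 genes, here called macrophage genes (called, log2 fold change of at least 3, outside the erythroid and heme biosynthesis lists). These were chosen by their fold change in the same libraries and not by known expression in macrophages. The first form, the median log2 ratio of Epor-eGFP+ library 2 to library 1, was −0.29. This value lay inside the 5th to 95th percentile (−0.32 to 2.38) of the 54 genes. It was below the 5th percentile (0.0054) without the 2 erythroid progenitor genes among the 54. In a second form, 7.69% of 13 genes, the 4 granule genes and the promyelocyte genes called higher, held the macrophage genes' order of the libraries, as did 5.56% of 18 with those not called, against 23.9% of all tested genes, and 11 of the 13 were highest in library 1, where macrophage genes were lowest. The values argue against a fixed ratio, while expression by these macrophages in a ratio that differs between libraries was not tested and stays open.

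Erythroid genes rose in the Epor-eGFP+ group, and 24 of the 25 called were highest in library 0. Of 12 further erythroid progenitor genes, 11 rose and 1 fell (median 1.42), which is consistent with erythroid progenitors in or attached to the Epor-eGFP+ material, and 2 of the 12 averaged at least 10 FPKM in Epor-eGFP- cells. Erythroblasts bound to a macrophage would pass the F4/80 gate with it, and whether the gate kept free ones out was not tested. Of the 54 macrophage genes, 48 were highest in library 2 and lowest in library 1, an order held by 4% of the called erythroid genes. All 40 tested, the globins among them, held it in 22.5%, against 23.9% of all tested genes. The first form was −0.16 for the called genes, above the macrophage genes' 5th percentile with all 54 (−0.32) and below it without the 2 (0.0054). For the called erythroid genes, the order argues against a fixed ratio to the macrophage genes. With the uncalled genes included, a fixed ratio stays open, and a ratio that differs between libraries was not tested. Globins had a median log2 ratio of Epor-eGFP- library 2 to library 1 of 4.41, but a gene that followed them would tend to lose its call, so the called erythroid genes do not decide the source of the globins.

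Macrophage genes differed between the Epor-eGFP+ libraries, as 48 of the 54 (88.9%) were highest in library 2 and lowest in library 1, against 23.9% of all tested genes, and their median log2 ratio of library 2 to 1 was 1.97. Of the 52 genes other than the erythroid progenitor genes, 4 break this order and thereby set the 5th percentile. A different share, in each library, of the cells that hold these genes would give a shared order. The genes were chosen by fold change, so the order does not show that these cells are macrophages. A scaling difference would move all genes alike, but the median log2 ratio over all tested genes was −0.045, inside the range of the 54 genes (−0.32 to 2.38) and below the 5th percentile (0.0054) without the 2 erythroid progenitor genes. In a second form, 88.9% still held the order after quantile normalization, and together these values argue against scaling. What would make this share differ was not tested, since the labels name no difference between these libraries.

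Of 19 genes listed at 0 in any library, Lyz2 and Prg2 exceed 100 FPKM in another, and the other 17 reach at most 4.01. With the 0 left out, the log2 fold change was −1.64 for Lyz2 and 0.17 for Prg2, against 2.82 and −4.29 with it.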
